A study of Mus musculus with 2 samples.

How the data were processed

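H3K9ac ChIP-seq was performed on lung of B6NCrl mouse embryos at embryonic day 16.5, with DNA fragments of 300 to 500 bp, per the labels. The 2 samples are biological replicates of 1 group, each from pooled male and female embryos and each with technical replicate number 1. The analysis started from 4 peak lists in narrowPeak format on build mm10, per the deposited description files, which also list the parents of each file. The list of replicate 1 was made from 1 alignment file and 2 control files, that of replicate 2 from 1 alignment file and 1 control file, and a joint list from 2 alignment files and 2 control files. The replicated list was derived from the other 3 peak lists. The aligner, the peak caller, its threshold and the rule by which the replicated list was made are not given in the sources used here. A difference in control files or read depth between the replicates can change how many peaks pass a caller's threshold.

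Each peak's signal value was written by the authors' peak caller and deposited without a definition, and it is taken as a signal relative to control. The −log10 p and −log10 q of each peak are also the authors' deposited values, and −log10 p was at least 2.0 in every list. These values were used only to describe, rank or filter peaks within a list. Read depth is unknown because the lists give no counts, so no interval or floor for counting error can be given. No list held overlapping entries.

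Peaks on chromosomes 1 to 19, X and Y were analysed, and those on other scaffolds (8 peaks in the list of replicate 1, 7 in that of replicate 2, 8 in the joint list and 7 in the replicated list) were left out. Genes and transcription starts came from GENCODE release M21, and sequence from assembly GRCm38.p6, which has the coordinates of mm10. Positions are counted from 1. A protein-coding gene was called marked when any of its transcription starts lay within 1000 bp of a replicated peak. Peaks of the replicates were matched by an overlap of at least 1 bp. Overlaps and promoter shares were compared with 100 circular shifts of the peaks within each chromosome, with a random seed of 20, and the smallest p such shifts give is 0.0099. Gene lists fixed before the data were examined were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 21 lists: alveolar, airway and general epithelium, mesenchyme, smooth muscle and pericytes, endothelium, mesothelium, immune, erythroid, branching signals, cell cycle, ribosomal proteins, neuronal, hepatocyte, cardiomyocyte, skeletal muscle, germline, olfactory receptors, and Hox groups 1 to 5, 6 to 8 and 9 to 13. Adjusted p under 0.05 passed. Beside each test stands the percentile of the list's marked share among 10000 random lists matched on the observed to expected CpG ratio within 500 bp of each gene's most 5′ start, in 20 bins. A gene marked at another start than this one can therefore be matched to genes of lower CpG content. Peaks and genes are not replicates, so these p-values describe the lists and not the spread between embryos.

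Wide domains were made by joining replicated peaks at most 1000 bp apart and taking the widest 1%, with marked genes as the background. Distal peaks lay over 2500 bp from every annotated start of any gene type. They were counted within 50 kb of each marked gene's most 5′ start and compared with 100000 random lists of marked genes, for lists of at least 5 genes. Motif consensus sequences of 16 families, also fixed beforehand, were searched on both strands within 250 bp of distal summits and in windows 5 kb to either side outside all peaks, matched on GC content in bins of 2 percentage points. Of 12747 distal windows, 9436 found a match.

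The genes named were fixed by a rule set before the data were examined: 25 anchor genes whatever their values, the 3 members with the highest signal value in each list of up to 30 genes, the unmarked members of such a list where there were 5 or fewer and otherwise the first 5 in alphabetical order, the genes at the 12 widest domains, the 10 genes with the most distal peaks within 50 kb, and the most posterior marked gene of each Hox cluster. Genes outside this rule are named where a count of marked genes was small or where the text says so.

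Alternatives were a −log10 q of at least 5, a signal value of at least 4, the joint list in place of the replicated list, the list of each replicate alone, an overlap of 50% of either peak, merging of overlapping peaks, ranks by −log10 p, a promoter window of 2500 bp, only the most 5′ start, joining distances of 0 and 3000 bp, the widest 5% of domains, a distal distance of 5000 bp, genes within 100 kb, motif windows of 100 bp to each side, and shuffled sequences as controls. After the data were seen, peaks found in each replicate list were added as an alternative.

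The tests were tried on simulated data. On all 21938 genes, gene lists of 20 genes with 97% marked were recovered in 99 of 100 cases and lists with 20% marked in 100 of 100, against 64% in other genes, and 3 of 200 unchanged lists were called. For distal peaks, 91 of 100 raised lists were recovered and 3 of 300 unchanged lists called. In these simulations each gene was drawn independently and without regard to CpG content. Real neighbouring genes share peaks and real marking follows CpG content, so these rates do not carry over to the real lists. A motif planted in 10% of 5974 windows was found in 10.1% of them and in 0.285% of controls, and none of 15 other families was called. Planted overlaps of 9.87%, 50.0% and 90.3% between simulated lists of 20000 peaks were measured as 10.4%, 50.2% and 90.3%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1 indexed the genome.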

Results

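Acetylation of lysine 9 on histone H3 (H3K9ac), a chromatin mark found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the lung of B6NCrl mouse embryos at embryonic day 16.5. At this stage the branched airway tree has formed and the distal epithelium begins to differentiate. Both samples belonged to 1 group and were biological replicates, each made from lungs of male and female embryos pooled together. The replicate 2 pool came from 41 embryos, and the labels give no number for replicate 1. With no treated or control group, the design implies a description of the marked genes and regions and a comparison of the replicates. The peak list of replicate 1 held 65282 peaks covering 38.1 Mb, and that of replicate 2 held 38375 peaks covering 26.5 Mb. A list called on both replicates together held 51061 peaks. The replicated list, which the authors derived from these 3 lists, held 39217 peaks covering 33.7 Mb, or 1.24% of the chromosomes. Its peaks had a median width of 583 bp and a median signal value of 5.11 (highest 50.8). Read depth is unknown, since the files give no read counts. Signal values are the authors' own value for each peak and are used here only to describe, rank or filter peaks within a list. Unless another list is named, values below are from the replicated list, on build mm10.

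The promoters of most protein-coding genes carried H3K9ac in the fetal lung, and the mark followed the CpG content of the promoter. Of 21938 protein-coding genes, 14132 (64.4%) had a peak within 1000 bp of an annotated transcription start, and these genes are called marked below. The marked share was 6.24% in the tenth of genes with the fewest CpG dinucleotides at the promoter and 97.7% in the tenth with the most. Over marked genes the median signal value was 18.0, with 10.7 and 24.6 as the lower and upper quartiles. Of 39210 peaks on the chromosomes, 20733 (52.9%) lay within 1000 bp of such a start, against a mean of 5.35% and a highest value of 6.09% over 100 circular shifts of the peaks within each chromosome. The one-sided permutation p was 0.0099, the smallest that 100 shifts can give.

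Reference genes of the lung's main tissues were marked, and those of blood cells and other organs were not. Nkx2-1, the transcription factor that specifies lung epithelium, had a peak at chromosome 12, 56532869 to 56539050, over its annotated start, with a signal value of 17.8. Sftpc, which encodes surfactant protein C, had a peak of signal value 29.9 at chromosome 14, 70518503 to 70523487, which also reached the start of the neighbouring gene Bmp1. This value followed replicate 1, whose own list gave 28.2, whereas the list of replicate 2 gave 6.86 at Sftpc, below its values of 15.9 at Sox9 and 14.8 at Etv5. Sftpb, for surfactant protein B, had a weaker peak of 4.28. Among other epithelial regulators, the signal value was 22.2 at Sox9 and 17.2 at Etv5, both active in distal tips, 15.6 at Foxa2, 13.9 at Shh, the hedgehog ligand of the epithelium, and 7.05 at Sox2, a factor of the proximal airway. In the mesenchyme, the peaks at Tbx5, Tbx4 and Foxf1, transcription factors of the lung mesoderm, had values of 21.7, 21.4 and 20.4. Genes of the secreted mesenchymal ligands Wnt2 and Fgf10 had peaks of 10.1 and 7.87. At genes of endothelium and smooth muscle, the signal value was 15.96 at Kdr, a receptor for vascular endothelial growth factor, 6.38 at Pecam1 and 9.58 at Acta2, which encodes smooth muscle actin. Wt1, a mesothelial transcription factor, had a peak of 3.41, with no peak at its promoter in either single-replicate list. The broadly expressed genes Actb and Gapdh had values of 48.7 and 23.1. No replicated peak lay at Ptprc (leukocytes), Hba-a1 (red cells), Alb (liver), Neurod1 (neurons), Myh6 (heart muscle) or Myod1 (skeletal muscle). Of these 6 genes, Myh6 had a peak in the list of replicate 1, with a signal value of 2.52.

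Genes of epithelium, mesenchyme, endothelium and branching signals were marked almost without exception. Of 21 gene lists fixed beforehand, 6 were marked more often than other genes, 7 less often, and 8 did not pass the test. All 26 branching genes were marked, with the highest values at Smo, the hedgehog signal transducer (signal value 40.5), Dusp6, a feedback inhibitor of FGF signalling (32.3), and Axin2, a Wnt target (31.7). In the list of replicate 2 their order was reversed, with 25.5 at Axin2, 24.8 at Dusp6 and 23.8 at Smo. All 19 genes shared by epithelia were marked, with the highest values at Foxa1 (19.4), Cdh1 (17.9), which encodes E-cadherin, and Spint2 (17.4), a protease inhibitor. Replicate 2 alone gave 16.9, 8.64 and 9.20 at these genes. All 22 endothelial genes were marked, led by Fli1 (21.3), an ETS transcription factor, Egfl7 (18.3) and Eng (16.3), which encodes endoglin. The Egfl7 peak also reached the start of Gm20532. In the mesenchyme 22 of 23 genes were marked, with 25.4 at Tbx2, 23.4 at Tbx3 and 22.4 at Vim. Vim stood above both in the list of replicate 1 (24.8, against 22.7 and 22.5) and below both in that of replicate 2 (13.9, against 21.9 and 19.4). The exception was Lum, for the matrix proteoglycan lumican, which had a peak in the list of replicate 1 and in that of both replicates together, but not in that of replicate 2. Median signal values of the marked genes were 21.5 for branching, 14.8 for mesenchyme, 11.7 for epithelium and 8.41 for endothelium, against 18.0 over all marked genes. At a signal value of at least 4, 19 of 22 endothelial genes stayed marked. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted over 21 lists, with adjusted p = 4.84e-05 for branching, 7.89e-04 for epithelium, 1.95e-04 for endothelium and 1.44e-03 for mesenchyme. Each of these shares stood at percentile 99.85 or above among 10000 random lists matched on promoter CpG content, although the branching share stood at percentile 94.1 when the highest CpG ratio over each gene's starts was matched. The branching list shares Fgf10 and Wnt2 with the mesenchyme list, and Fgfr2 and Bmp4 with the alveolar list, so results of these lists are not fully independent. The peak read at Fgfr2 also reached the start of Ctbp2, as described below.

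Lists of the differentiated cell types of the lung were marked in part. Of 22 alveolar genes, 19 were marked, with the highest values after Sftpc at Lpcat1 (27.5), an enzyme of surfactant lipid synthesis, and Fgfr2 (24.99), the receptor for Fgf10. The Fgfr2 peak, at chromosome 7, 133121080 to 133125431, also reached the start of Ctbp2. It lay at the far 5′ end of an annotated gene span that runs from 130162451 to 133123350. The value can therefore belong to Ctbp2, and whether another Fgfr2 start had a peak is not given here. Distal peaks of Fgfr2 were also counted from this far start. In the list of replicate 2 the value at Fgfr2, read in the same way (19.2), stood above Lpcat1 (14.8). The unmarked genes were Lamp3, Sftpa1 and Sftpd, which belong to mature type II cells and surfactant. Of 17 airway genes, 10 were marked, with 25.6 at Hes1, a Notch target, and 12.1 at Foxj1 and 11.7 at Ccno, both of multiciliated cells. The secretory genes Scgb1a1, Scgb3a1 and Cyp2f2 and the basal-cell keratins Krt5 and Krt14 were among the 7 without a peak. Of 13 smooth muscle and pericyte genes, 11 were marked, led by Notch3 (14.5), Cspg4 (13.7) and Acta2, and the contractile genes Actg2 and Cnn1 were not. The Cspg4 peak also reached the start of Odf3l1. Of 9 mesothelial genes, 5 were marked, with the highest values at Wnt2b (8.11), Aldh1a2 (5.54) and Bnc1 (3.52), and Lrrn4, Muc16, Upk1b and Upk3b were not. None of these 4 lists differed from other genes by Fisher's exact test, with adjusted p = 0.0633 for alveolar, 0.652 for airway, 0.205 for smooth muscle and 0.730 for mesothelial genes. Among random lists matched on promoter CpG content, the alveolar share stood at the 99.9th percentile and the smooth muscle share at the 99.1th. Smooth muscle genes passed the test in the list of replicate 1, where 13 of 13 were marked (adjusted p = 0.0125, exact), and in the list of both replicates together (0.0102). Mesothelial genes were marked less often than others at a −log10 q of at least 5 (adjusted p = 0.0486, exact) or a signal value of at least 4 (0.0485).

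Among blood cell genes, few immune genes and a number of erythroid regulators were marked. Of 17 immune genes 2 were marked, Coro1a (5.70) and Spi1 (2.92), and Adgre1, Cd3e, Cd53, Cd68 and Cd79a were among the unmarked. Their share was lower than that of other genes (adjusted p = 4.68e-05, exact), but it stood at the 7.39th percentile of lists matched on CpG content, inside the middle 95% of those lists. In the list of replicate 1, 7 of the 17 were marked, and the difference no longer passed the test there (adjusted p = 0.0580, exact). Of 13 erythroid genes 5 were marked, led by Klf1 (24.8) and Nfe2 (12.9), transcription factors of red cell precursors, and Epor (9.69), the erythropoietin receptor. The globin genes Hba-a1, Hba-a2 and Hbb-bs, the heme synthesis gene Alas2 and the transcription factor Gata1 were unmarked. The erythroid share did not differ from that of other genes (adjusted p = 0.109, exact). A gene of this list, Ahsp, was not found by that symbol in the annotation.

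Genes of liver, germline, neurons, skeletal muscle and olfactory receptors were marked less often than other genes, and those of heart muscle were not. None of 18 hepatocyte genes was marked, among them Afp, Ahsg, Alb, Apoa1 and Apob (adjusted p = 5.78e-08, exact), and none of 1135 olfactory receptor genes was. Of 17 germline genes 3 were marked, Dazl (13.7), Tnp2 (3.82) and Tdrd1 (2.93), with adjusted p = 2.46e-04 in the exact test. Neither replicate's own list had a peak at Tnp2, and only that of replicate 2 had one at Tdrd1. Of 17 neuronal genes 5 were marked, with the highest values at Map2 (12.3), Slc17a7 (8.34) and Elavl4 (7.77), and adjusted p = 6.60e-03 in the exact test. Of 16 skeletal muscle genes 4 were marked, but the peaks at Mylpf (27.6) and Ckm (10.2) also reached the starts of Tbc1d10b and Klc3, and Tnni2 followed with 7.54 (adjusted p = 4.22e-03, exact; 0.0505 with a window of 2500 bp). Of 14 cardiomyocyte genes 8 were marked, a share that did not differ from other genes (adjusted p = 0.652, exact) and stood at the 96.0th percentile of lists matched on CpG content. The highest values of this list were at Tnnc1 (30.6) and Myl3 (14.2), whose peaks also reached the starts of Nisch and Pth1r, and at Ryr2 (7.90), and the peaks of 6 of the 8 genes reached no other gene. In the list of replicate 2 the value at Tnnc1 was 10.7, and in that of replicate 1 no peak lay within 1000 bp of its start. Myh6, Nkx2-5, Nppa, Nppb and Pln were unmarked. The germline and neuronal shares lay below all 10000 matched lists, whose medians were 58.8% and 76.5%. The hepatocyte share lay at percentile 0.02 and the skeletal muscle share at percentile 3.02, inside the middle 95%. With the highest CpG ratio over each gene's starts, the cardiomyocyte share moved to percentile 98.9, outside the middle 95%, and the skeletal muscle share to percentile 11.3.

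Broadly used genes were nearly all marked. All 22 cell cycle genes had peaks, with 29.1 at Cdk1, 26.9 at Ccnb2 and 26.2 at Mcm4, and so did 77 of 80 ribosomal protein genes, the exceptions being Rpl10l, Rpl39l and Rpl3l. Both shares exceeded that of other genes (adjusted p = 1.95e-04 and 1.16e-10, exact). The cell cycle share stood at the 86.9th and the ribosomal share at the 98.2th percentile of lists with the same promoter CpG content. With the highest CpG ratio over each gene's starts, the ribosomal share stood at percentile 63.2, inside the middle 95%. The Mcm4 peak also reached the start of Prkdc. In all, the peaks of 3 of the 22 cell cycle genes and 16 of the 77 marked ribosomal genes also reached another gene.

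**Figure D1:**
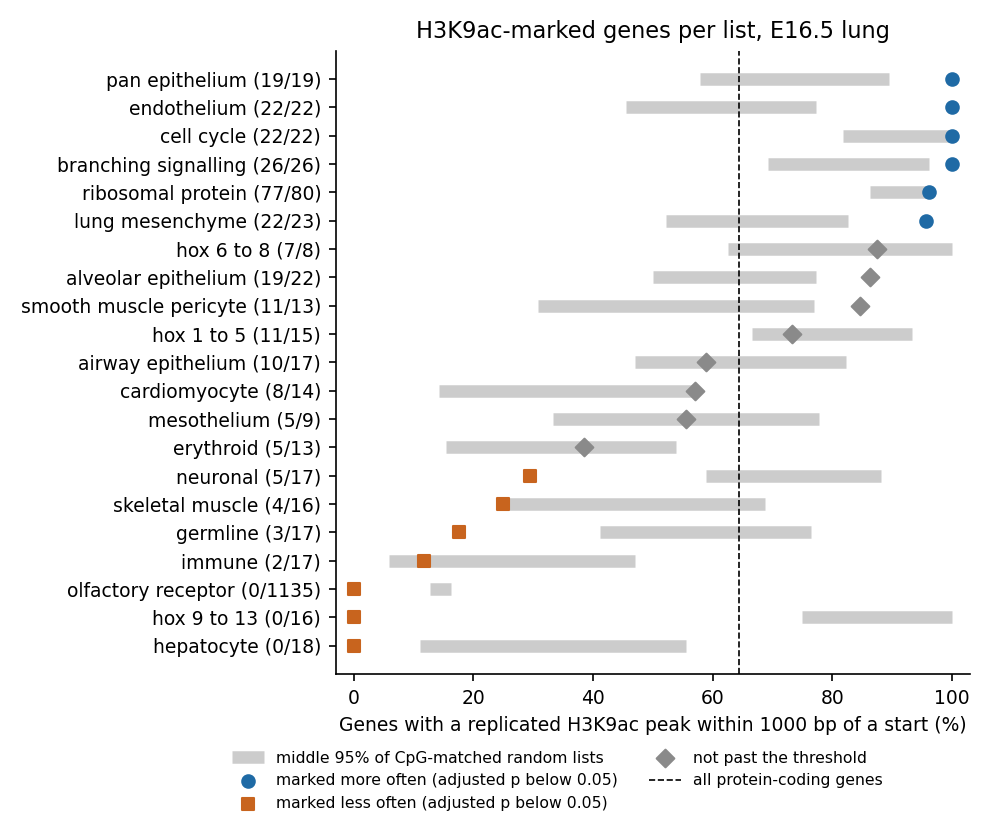
Share of marked genes in each of the 21 gene lists (points, in percent, with the number of genes) for the replicated list, with grey bars for the middle 95% of 10000 random gene lists matched on promoter CpG content and the dashed line the share over all protein-coding genes. Hox groups 9 to 13 stood at 0% where matched lists had a median of 93.75%.

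Within the Hox clusters, whose genes set position along the body axis, the mark covered anterior genes of the Hoxa and Hoxb clusters and stopped before the posterior ones. Of 15 genes of groups 1 to 5, 11 were marked, and of 8 genes of groups 6 to 8, 7 were marked. None of 16 genes of groups 9 to 13 was marked, although random genes of the same CpG content had a median marked share of 93.75% (adjusted p = 3.43e-07 against all other genes, exact). Groups 1 to 5 and 6 to 8 did not differ from other genes (adjusted p = 0.652 and 0.338, exact). The most posterior marked genes were Hoxa7 (signal value 16.1), Hoxb8 (6.59), Hoxc6 (3.24) and Hoxd8 (3.49), and Hoxd8 was the only marked gene of its cluster. The strongest Hox peak at a start was that of Hoxa5, a regulator of lung development, with 29.7 at chromosome 6, 52199775 to 52204428. The share of groups 1 to 5 exceeded that of groups 9 to 13 by 73.3 percentage points (two-sided Fisher's exact test, p = 1.61e-05). Neighbouring Hox genes share peaks, so they are not independent. In the list of replicate 1, Hoxb9 also had a peak, with a signal value of 2.79.

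**Figure D2:**
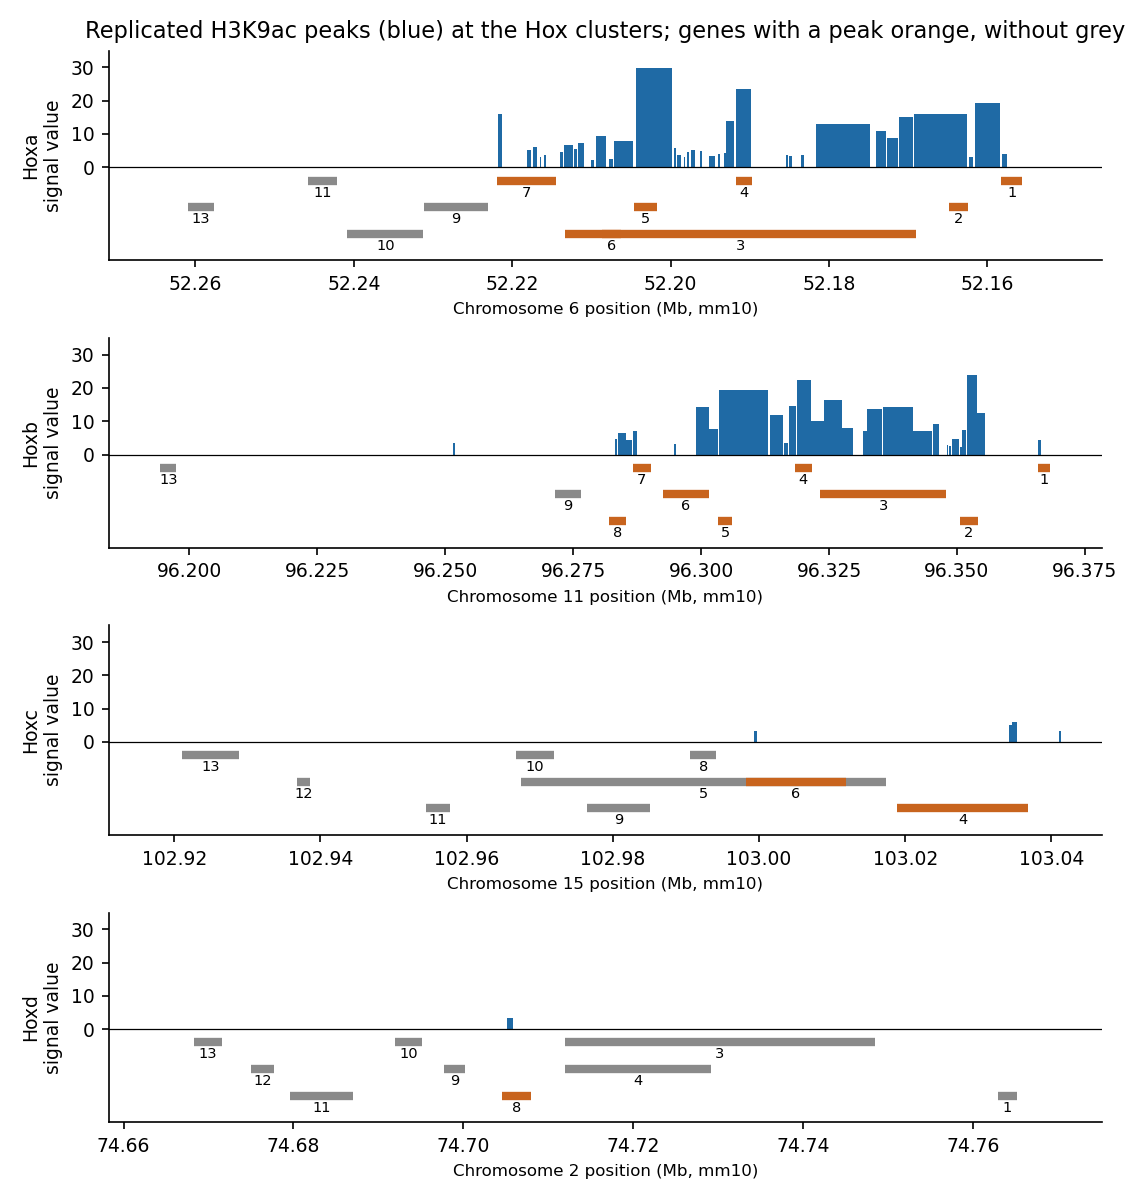
Replicated peaks at the 4 Hox clusters, with position on mm10 in Mb on each horizontal axis and the peak's signal value on the vertical axis (blue bars, drawn to scale). Gene bodies, labelled with their group number, are orange where the gene was marked and grey where it was not, and peaks end at Hoxa7 and, apart from a single peak between Hoxb9 and Hoxb13, at Hoxb8.

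Wide stretches of H3K9ac lay over anterior Hox genes and over genes of the branching, mesenchyme and alveolar lists. Peaks at most 1000 bp apart were joined into 26758 domains, and the widest 1% of them, 268 domains of at least 6044 bp, held the starts of 303 protein-coding genes. The widest spanned Hoxb3 to Hoxb6 over 30704 bp (chromosome 11, 96298979 to 96329682). It was followed by a domain of 25456 bp at Nr2f2, a nuclear receptor, at chromosome 7, 70345761 to 70371216. Domains of 24153 bp at Hoxa1 and Hoxa2 and of 24021 bp from Hoxa3 to Hoxa6 came next. That at Nkx2-1 measured 21439 bp (chromosome 12, 56517612 to 56539050). The rest of the 12 widest lay at Bahcc1 (19624 bp), Tbx2 (18911 bp), Nfib (18028 bp), Tbx5 (17559 bp), Zeb2 (16803 bp), Foxa1 (15966 bp) and Meis1 (15727 bp), most of which encode transcription factors. Among marked genes, the widest domains held 9 of 11 from Hox groups 1 to 5, 9 of 26 branching genes, 8 of 22 mesenchyme genes and 5 of 19 alveolar genes, against about 2.1% of other marked genes. In two-sided Fisher's exact tests adjusted over the 18 lists with marked genes, p was 8.12e-13, 1.74e-08, 6.02e-08 and 1.79e-04 for these lists. Neighbouring Hox genes lay in shared domains, such as that of Hoxa1 and Hoxa2, so they are not separate draws. The p of Hox groups 1 to 5 therefore overstates the evidence. Fgfr2 counts in both the branching and the alveolar list, and its domain of 8441 bp, at the far start described above, can likewise belong to Ctbp2. Hox groups 6 to 8, with 2 of 7 genes, gave adjusted p = 0.0323 in the exact test, and this call ended in the list of both replicates together (0.05005), without replicate 2 (0.0772) and with unjoined peaks, where the difference was −2.95 percentage points.

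Away from promoters, distal peaks were more numerous around branching and epithelial genes than around random marked genes. Of all peaks, 12748 (32.5%) lay over 2500 bp from every annotated start, with a median signal value of 3.69 and a median width of 372 bp. Marked genes had a mean of 1.13 such peaks within 50 kb of their start. The mean was 4.12 ± 5.35 (SD over genes, n = 26) for branching genes, 3.68 ± 3.64 (n = 19) for epithelial genes, 3.64 ± 1.63 (n = 11) for Hox groups 1 to 5 and 2.63 ± 2.36 (n = 19) for alveolar genes. Against random lists of marked genes in a two-sided permutation test, adjusted over 15 lists, p was 3.00e-04, 1.05e-03, 0.0187 and 0.0371 for these lists. The random lists were not matched on local gene density, which sets how much sequence near a gene can count as distal. Differences in gene density can therefore contribute to these results. The 22 endothelial genes had a mean of 2.32 and did not pass (adjusted permutation p = 0.0631). Neighbouring Hox genes have overlapping windows and had equal counts, with 5 at each of Hoxa1 to Hoxa5 and 2 at each of Hoxb3 to Hoxb5. The 11 Hox genes are therefore not independent, and their SD and permutation p overstate the evidence. The genes with the most distal peaks were Notch1, a receptor of cell fate choice, with 24, Smad7, an inhibitor of TGF-beta signalling, with 23, and Bahcc1 with 21. Notch1 is a member of the branching list and raised its mean, while the median of that list was 2.5, against 0 over marked genes. Sik1 had 20, Myh9 and Ncor2 had 19 each, and Ahdc1, Ankrd33, Btg2 and Irf2bpl had 18 each. Ankrd33 was itself unmarked. The number of distal peaks depended on the list: 4753 had a −log10 q of at least 5, and 19915 were distal in the list of both replicates together. The alveolar call ended under 5 alternatives and the Hox call under 4, among them without replicate 2 (adjusted permutation p = 0.445) and at a distance of 5000 bp, where the difference from all marked genes was −0.232 peaks. The epithelial call ended at a −log10 q of at least 5 (adjusted permutation p = 0.0838).

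The sequence around distal summits held consensus sites of several transcription factor families more often than sequence of the same GC content 5 kb away did. Within 250 bp of the summit, 12.8% of 9436 windows held a FOX consensus against 9.47% of these control windows, and 7.63% held an ETS consensus against 4.01%. The TEAD consensus was found in 10.6% against 7.84%, and the SP/KLF consensus in 3.90% against 2.33%. CTCF, the insulator protein, was found in 2.71% against 0.487% (odds ratio 5.69, and 2.77 in the list of replicate 1, without replicate 2). Two-sided Fisher's exact tests adjusted over 16 families gave p = 1.33e-12 for FOX, 9.42e-26 for ETS, 1.95e-10 for TEAD, 1.93e-09 for SP/KLF and 8.62e-36 for CTCF. NKX2, the family of Nkx2-1, was found in 5.74% against 5.03% (adjusted p = 0.0761, exact) and SOX in 3.02% against 2.46% (adjusted p = 0.0542, exact). The other families (AP1, NFI, GATA, RFX, PBX/MEIS, the E-box, NRF1, SRF and C/EBP) did not pass in this comparison. Few windows held NFI (8 against 2 controls), PBX/MEIS (20 against 25), the E-box (12 against 11), NRF1 (15 against 7) or C/EBP (7 against 12). For these families the test could have missed a difference. NKX2 passed in the distal peaks of replicate 1 (adjusted p = 7.10e-04, exact) and of replicate 2 (2.27e-03), and SRF in those of replicate 1 (3.57e-03), but both were rarer than in shuffled sequences, with differences of −2.68 and −0.792 percentage points. The ETS difference shrank from 3.62 to 0.957 percentage points against shuffled sequences (adjusted p = 9.41e-03, exact). Against these, NRF1 passed with 22 windows against 1 (adjusted p = 1.30e-05, exact) and C/EBP was rarer, with 9 against 49 (2.32e-07). FOX sites were fewer near the summit, with 8.94 to 11.8 per 1000 distal peaks in bins of 50 bp within 100 bp of it and 13.7 to 16.9 in those at 250 to 500 bp, without matching of GC content. CTCF sites lay to the sides of the summit and not on it, with 6.51 sites per 1000 distal peaks at 200 to 250 bp toward higher coordinates. The value was 5.18 at the same distance toward lower coordinates and 0.157 at 0 to 50 bp. Distances follow genome coordinates and have no strand. Within 100 bp of the summit the CTCF difference reversed, to −0.186 percentage points (adjusted p = 0.0165, exact), SP/KLF no longer passed (adjusted p = 0.766, exact), and AP1 was rarer, with 3.10% against 3.87% (adjusted p = 0.0170, exact). A consensus stands for a family of factors, and binding was not measured here.

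**Figure D3:**
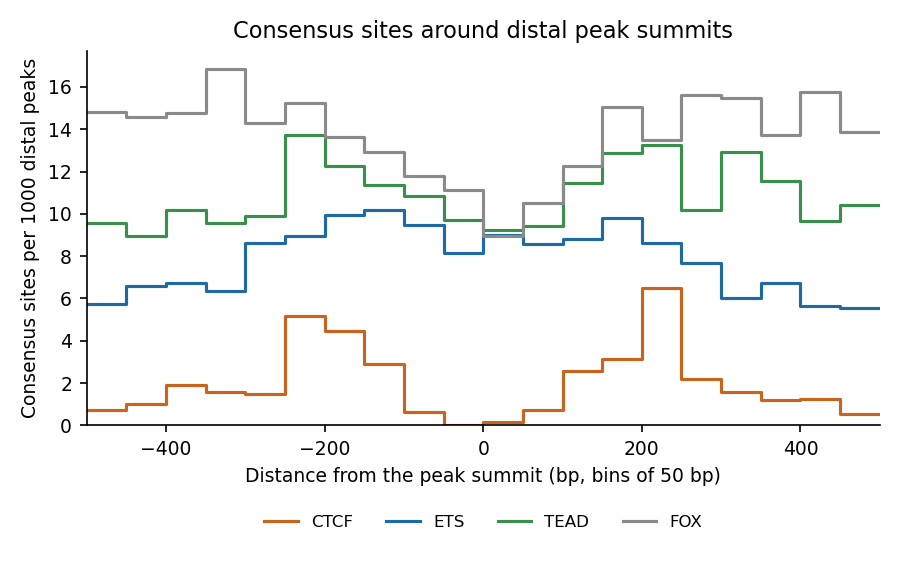
Consensus sites per 1000 distal peaks (vertical axis) by distance from the peak summit in bp, in bins of 50 bp (horizontal axis), for 4 motif families (lines). CTCF sites fell to 0 in the 50 bp on the lower-coordinate side of the summit and reached 6.51 per 1000 peaks at 200 to 250 bp on the other side.

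Genes on chromosome X were marked less often than those on autosomes. On X, 435 of 948 protein-coding genes (45.9%) were marked, against 13693 of 20807 (65.8%) on autosomes, and X held 5.05 peaks per Mb against 15.6. The odds ratio was 0.441 (two-sided Fisher's exact test, p = 1.96e-34). Chromosome 11 had 28.3 peaks per Mb. The Y chromosome had 4 peaks, at Kdm5d, Eif2s3y, Uty and Ddx3y, which are single-copy genes of its short arm. These 4 genes and chromosome 11 were named after their values were seen.

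The replicates shared their strong peaks and their promoters and differed in weak peaks away from promoters. At least 1 bp of overlap with replicate 2 was found for 47.3% of replicate 1 peaks (30859 of 65274), and 87.9% of replicate 2 peaks (33740 of 38368) overlapped replicate 1. Circular shifts gave at most 2.30% and 4.23% (one-sided permutation p = 0.0099 for each, the smallest that 100 shifts can give). In bases, the shared 23.9 Mb made up 62.8% of replicate 1 and 90.3% of replicate 2, with a Jaccard index of 0.589. Among the top 10% of each list by signal value, 100% of peaks had a counterpart in the other list, against 14.0% in the bottom 10% of replicate 1 and 66.2% in that of replicate 2. The p of each two-sided Fisher's exact test was too small to be represented. Shared peaks of replicate 1 lay at promoters in 63.0% of cases and had a median signal value of 7.35, whereas the 34415 peaks without a counterpart lay there in 16.1% and had a median of 3.26. In replicate 2 the shares were 63.4% for shared peaks and 18.7% for the 4628 others. Leaving out peaks with a −log10 q under 5 raised the overlap of replicate 1 to 71.0% and that of replicate 2 to 97.4%. Both replicates had a peak at 13751 genes, replicate 1 alone at 776 and replicate 2 alone at 91.

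**Figure D4:**
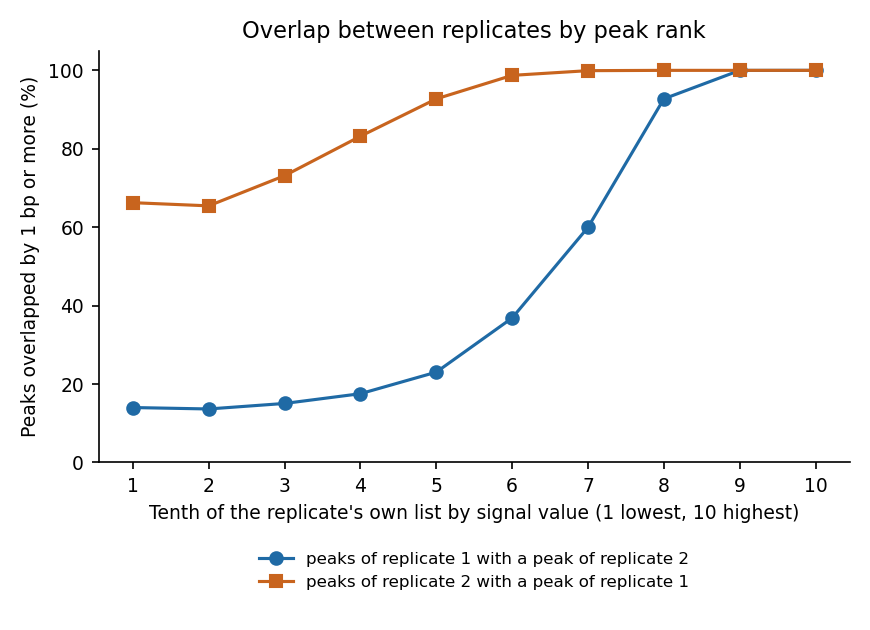
Percentage of peaks with a counterpart in the other replicate's list (vertical axis) by rank of signal value in steps of 10% of a replicate's peaks, from weakest to strongest (horizontal axis), with 1 line per replicate. The weakest 10% of replicate 1 stood at 14.0% and that of replicate 2 at 66.2%, and both lines reached 100%.

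The replicated list was not the intersection of the replicate lists. All of its 39210 chromosomal peaks had the coordinates of a peak called on both replicates together. Of them, 28491 (72.7%) overlapped a peak of each replicate list by 50% of either peak, with 64.3% at promoters and a median signal value of 8.05. A further 7889 (20.1%) overlapped only replicate 1 and 1537 (3.92%) only replicate 2. The remaining 1293 (3.30%), 18.3% of them at promoters, met this overlap in neither list.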

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

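Peaks outside the chromosomes entered no comparison, and they were examined after the other results were seen. The count was 7 in the replicated list, on 3 unplaced or unlocalized scaffolds. It is given because these peaks lie in data that the comparisons do not use, and no expected number was available. Signal values of these peaks ran from 2.497 to 24.1. The lists of replicate 1 and replicate 2 held 8 and 7 peaks on such scaffolds. No explanation was tested, and the genes on these scaffolds were not analysed here.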

How the results depend on the processing

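The alternative that keeps only peaks found in each replicate list was chosen after the data were seen, and the other alternatives were planned. Of 647 alternative values, 597 kept their side of the threshold, with the same direction where they passed it, or stayed within 1.5 times of a count. Where neither the main nor the alternative value passed, a change of direction was not counted. Mesothelial genes, for example, were marked in 55.6% against 64.4% of other genes in the main comparison and in 66.7% against 65.6% in the joint list. Marked genes ranged from 13319 to 14527. The causes of the changes below were not tested, except that stricter filters leave fewer peaks by construction. A −log10 q of at least 5 left 25938 peaks in replicate 1, 19988 in replicate 2, 25154 in the joint and 24993 in the replicated list, and a signal value of at least 4 left 29483, 25185, 25667 and 25406. Distal peaks numbered 4753 and 4989 under these filters, 19915 in the joint list, 6760 among peaks found in each replicate list, and 10523 to 29132 when a replicate was left out, with the higher value without replicate 2. Lists with more distal peaks fell from 4 to 2 at a −log10 q of at least 5, in the joint list and with a distance of 5000 bp. Motif families found more often fell from 5 to 3 within 100 bp of the summit, where 2 were found less often, and 3 were found less often than in shuffled sequences, against 0 in the main comparison.

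Single lists and motif families gave 14 lost calls, 12 gained calls and 5 reversals among 520 values. A reversal was counted only where the main or the alternative value passed. The reversals, in percentage points, were −2.95 for Hox groups 6 to 8 in wide domains with unjoined peaks, −0.186 for CTCF within 100 bp of the summit, and −2.68 for NKX2 and −0.792 for SRF against shuffled sequences. In mean distal peaks, Hox groups 1 to 5 reversed to −0.232 at a distance of 5000 bp. Without replicate 1 or replicate 2, NKX2 passed its exact test (adjusted p = 2.27e-03 and 7.10e-04), and the range over its alternatives reached 0.766. No paired analysis was possible because the samples form 1 group. Depth is unknown, so a missing weak peak does not show that the mark was absent.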

Other observations

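The gene families and noncoding genes described here, the tests of cell type genes in replicate 1, of the position of motif sites and of the highest CpG ratio over a gene's starts, and the use of peak rank and shuffled sequences to weigh explanations were chosen after the results were seen, although overlap by rank and shuffled controls had been planned as comparisons; the other tests were chosen before their results were seen. Beyond the lists fixed beforehand, 25 gene families were counted. They were chosen after genes in wide domains and unmarked genes had been seen, so the counts are descriptive and no test is given. Wide domains held 11 of 39 marked genes of the immediate-early and feedback families (Jun, Fos, Egr, Ier, Dusp and Zfp36 relatives), among them Jun, Junb, Jund and Ier2. They also held 5 of 9 marked T-box genes, 4 of 5 Irx genes, 5 of 11 Meis and Pbx relatives, 5 of 11 Id and Hes genes and 3 of 4 Nfi genes, against about 2.1% of other marked genes. They held none of 16 Sox, 8 Pou, 8 Lhx, 5 Dlx and 8 neural bHLH genes that were marked, and 8 of 340 Zfp genes (2.35%). Among noncoding genes, 917 of 5854 lincRNA genes (15.7%) were marked, and 11.04% of those away from protein-coding starts. Wide domains also lay at Carmn, a noncoding RNA of smooth muscle (15441 bp, chromosome 18, 61651057 to 61666497), and at Malat1 (10938 bp, chromosome 19, 5796310 to 5807247). Xist, which is expressed from the inactive X, had a peak with a signal value of 10.2, and the imprinted genes H19 and Meg3 had values of 11.8 and 8.62.

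Among CpG-rich promoters, some of those that lacked the mark belonged to families with roles in other tissues. Of the 10969 genes with an observed to expected CpG ratio of at least 0.552, 555 (5.06%) were unmarked. The unmarked share was 20 of 31 for Hox genes and 21 of 37 for protocadherins, neuronal adhesion genes expressed from alternative promoters. It was 8 of 11 for Nkx genes, a family that includes the marked Nkx2-1, and 7 of 13 for neural bHLH genes such as Neurog1 and Olig2. For Pax genes it was 5 of 7, with Pax3 and Pax7 among them, and for potassium channels 10 of 40. Neighbouring Hox and protocadherin genes lie in clusters and are not independent. Among Zfp genes 4 of 221 were unmarked.

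Replicate 1 had 34415 peaks without a counterpart in replicate 2. Background calls placed at random are argued against as the source of all of them. Of the 21775 distal ones, 32.9% lay within 5 kb of a shared peak, compared with at most 10.5% in 100 circular shifts. The shifts cannot tell whether part of these peaks are random calls, or whether background calls are themselves unevenly placed, so both stay open. Lower power in replicate 2 stays open: 0.00766% of the strongest 20% of replicate 1 peaks (1 of 13055) lacked a counterpart, compared with 52.7% of all, but this restates the pattern, and read depth is unknown. More immune cells in the replicate 1 pool stay open as well: of 15 immune genes without a replicate 2 peak, Cd68, Cd79a, Csf1r, Fcer1g and Tyrobp had a replicate 1 peak, the 99.8th percentile of lists matched on CpG content, but Actg2, Cnn1 and Tagln of smooth muscle, 3 of 3, stood as high (99.9th), so the excess was not specific to immune genes. The replicates form 1 group, so no biological explanation named by the design was tested.

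CTCF consensus sites lay beside distal summits and were nearly missing from their centres. The GC matching of the control windows is argued against as the cause of the excess within 250 bp, since the odds ratio was 7.16 with shuffled sequences as controls. This ratio does not concern the position of the sites, and their profile around summits used no control windows. For the position, a property of summits shared to the same degree by all motifs is argued against. Of FOX, ETS and TEAD windows, 34.8% to 39.2% held their site within 100 bp, against 4.66% of CTCF windows. A weaker dip shared with other motifs stays open, since the FOX and TEAD shares lay somewhat below that of even spacing. TEAD sites numbered 9.26 to 10.8 per 1000 distal peaks within 100 bp, and 13.3 and 13.7 at 200 to 250 bp. ETS lay near even spacing, and SP/KLF, which lost its excess within 100 bp of the summit, was not profiled. Acetylated nucleosomes flanking sites occupied by CTCF, which would place summits off the site, stay open: the share of CTCF windows with the site within 100 bp was 9.29% in the list of replicate 1 and 5.71% in that of replicate 2, which restates the pattern, and no binding or nucleosome data were analysed here. No biological explanation named by the design was tested.

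Chromosome X had a lower share of marked genes than autosomes. Promoter CpG content is argued against as the whole cause, since 45.9% of X genes were marked and the middle 95% of matched autosomal lists ran from 55.1% to 59.7%. Gene copies with near-identical promoters, 19.7% of X genes and 4.29% of autosomal ones, make up part of the gap. Without them 56.9% of 761 X genes were marked, below the lowest of 10000 matched lists (58.6%). When the highest CpG ratio over a gene's starts was matched, this share was not below the lowest list (56.4%). It still lay below the middle 95% of those lists (58.6% to 63.1%). A lower signal per promoter on X, as a single active X in each cell could give, remains open, since marked X genes had a median signal value of 11.5 and matched autosomal genes 15.9 (14.8 to 17.0). Both samples pool sexes, so no biological explanation could be tested between groups.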
